A study of Escherichia coli with 4 samples.

How the data were processed

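RNA was sequenced from Escherichia coli K-12 BW25113, either wild type or with the dps gene deleted, carrying either an empty pACYC vector or a plasmid that overproduces the small RNA DsrA. Per the labels, overnight cultures were diluted 5000-fold, grown at 42 °C to an OD450 of 0.15 to 0.2, and 3 biological replicates were combined into each library. From 1 microgram of total RNA, ribosomal RNA was depleted, strand-marked libraries were made, and paired reads of 150 bases were taken on a NovaSeq instrument. Each of the 4 groups therefore has 1 library.

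The deposited table holds, for 4198 genes and each library, an expected count and an FPKM value. The expected counts are estimated read counts per gene made by the authors with Bowtie2 2.2.8 and RSEM. The deposited FPKM values divide each count by gene length and by the total assigned count of the library. The submitters also name edgeR. The genome build, the gene annotation and the RSEM version are not given in the sources used here. Of the 4198 genes, 27 carried a fractional count in at least 1 library, and counts were rounded to whole numbers. Symbols were taken from the table. Gene names and neighbours were checked against the annotation of the E. coli K-12 assembly ASM584v2, and 54 genes had no symbol.

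Total counts were 2742250 for wild type with vector, 1939001 for wild type with the dsrA plasmid, 3433311 for the dps deletion with vector and 3150425 for the dps deletion with the dsrA plasmid. Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 0.974, 0.999, 1.03 and 0.999 in the same order. Log2 ratios between libraries were taken from log2 CPM, which are counts scaled to library size, with a prior count of 2. A gene was counted as higher or lower where its log2 ratio was at least 1 in size and at least 1 of the 2 libraries had 50 or more counts. A difference between the plasmid effects of the strains was counted where the log2 ratios differed by at least 2 and at least 1 of the 4 libraries had 50 or more counts.

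Folds are ratios of scaled counts without a prior, with exact 95% Clopper-Pearson intervals conditional on the sum of both counts. Where 1 library had 0 counts, the fold is a lower bound against a floor of 3 counts in that library, which equals 1.12, 1.55, 0.849 and 0.953 CPM in the order above. These intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules. With 1 library per group no test against replicate variation was made, and no p-value is given across genes.

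In advance, 39 gene lists with 862 entries were fixed, of which 800 entries matched the table. For each list, the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean level in 10 bins, and called outside where it left their central 95%. In 36 lists a median could be placed. Genes of an operon or regulon move together, which random lists do not, so the percentile describes these libraries and is not a p-value. KEGG pathways with at least 8 measured genes, as annotated in the deposited table, were treated in the same way after the data had been seen. The dps gene was left out of list medians except where wild-type libraries were compared, and of correlations.

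The named genes were chosen by a rule: dps, rpoS, hns, rbsD, mreB, dnaA, seqA and hda in each comparison, the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among those counted, the 8 largest differences between strains in each direction, and the 4 members with the largest ratio in each list outside its random range. Other genes named are members of the operons or lists described and were chosen after their values were seen.

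For the flagellar list, which had few genes with 50 counts in 3 of the libraries, counts were also summed over genes and compared without a prior, after the data had been seen. The interval of 1 median in the closing part is a bootstrap over genes with 10000 draws, which treats genes as independent.

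Alternatives changed 1 choice at a time, except that the FPKM values bring their own scaling and a pseudocount of 1. They used DESeq2 1.42.0 size factors, library totals or upper-quartile scaling, filters of 10, 200 or 1 count, prior counts of 0.5 or 10, the deposited FPKM values, libraries thinned to the smallest total, and scaling without the 10 highest genes. An alternative with an even background removed from the wild-type library with the dsrA plasmid was chosen after seeing the data. The steps were tested on simulated data, where 22 of 50 genes set to a 2-fold change and 50 of 50 set to a 3-fold change were recovered. The simulated counts held counting noise only. The changed genes had an expected count of at least 50 in wild type with the dsrA plasmid before the change. Recovery of weaker genes, or with variation between culture pools, was not simulated. Counting noise alone brought 2 of 2345 unchanged genes past the limit in the wild-type plasmid comparison. Of 200 simulated lists of randomly drawn genes without a shift, 7 fell outside the random range. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.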

Results

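Transcript levels were measured in 4 libraries of E. coli grown at 42 °C, 1 for each combination of 2 strains and 2 plasmids. The strains were wild type and a deletion of dps, which encodes the DNA-binding protein of starved cells. The plasmids were an empty vector and one overproducing DsrA, a small RNA known to stimulate translation of rpoS and to lower that of hns. Total counts ranged from 1939001 in wild type with the dsrA plasmid to 3433311 in the dps deletion with vector, and between 3964 and 4022 genes had a count in each library. The 10 most abundant genes took 14.6% to 15.7% of the counts of a library. Each library pooled 3 biological replicates, so differences between libraries have no replicate check, and the intervals in brackets after folds and ratios cover counting error only.

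The deleted gene dps (BW25113_RS04220) had 0 counts in both libraries of the deletion strain. In wild type dps had 61 counts with the vector and 241 with the dsrA plasmid, which were 22.8 and 124 CPM. Relative to wild type, dps was at least 26.9-fold lower in the deletion with vector and at least 131-fold lower in the deletion with the dsrA plasmid. The deposited values have no entry for dsrA, so its level could not be read and the plasmid label has no direct check in the counts.

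The first comparison asked which transcripts differed with the dsrA plasmid in wild type. Genes for acid resistance were higher with the plasmid, led by gadA, a glutamate decarboxylase, at 30.5-fold [16.7 to 61.8], the regulator gadE at 22.4-fold [13.9 to 38.3] and the periplasmic chaperone hdeA at 20.6-fold [13.6 to 32.6]. The nucleoid protein genes hns, at 3.91-fold [3.69 to 4.15], and its paralog stpA, at 4.95-fold [3.36 to 7.47], were higher, as was dps itself at 5.45-fold [4.10 to 7.34]. Of 13 measured nucleoid-associated protein genes, these included, 4 were at least 2-fold higher, and the list median of 0.03 lay inside the random range. The ferrichrome receptor gene fhuA was 35.3-fold lower [27.6 to 46.0], and fimA, the major subunit of type 1 fimbriae, was 30.2-fold lower [22.6 to 41.4]. Of 2555 measured genes, 164 were at least 2-fold higher and 27 at least 2-fold lower, and a filter of 200 in place of 50 counts left 49 and 14.

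In wild type with the dsrA plasmid, 14 of 14 measured acid resistance genes were at least 2-fold higher, with a median log2 ratio of 3.18 at percentile 100 of the random lists. Members included slp, an outer membrane lipoprotein, at 11.4-fold [7.71 to 17.3] and hdeB at 14.3-fold [9.05 to 24.0]. The values of gadA and gadB are uncertain, since these near-identical copies share reads. Of 26 measured RpoS-dependent stress genes, 15 were at least 2-fold higher, with a median of 1.21 at percentile 100. Among them, dosC, a cyclic di-GMP synthase, was 13.3-fold higher [6.71 to 30.1], hchA, a chaperone, 5.21-fold [4.13 to 6.64], and otsB, of trehalose synthesis, 3.84-fold [2.94 to 5.07]. The rpoS transcript itself had a log2 ratio of -0.08. Of 11 measured H-NS-silenced genes, 8 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.26 outside the random range. They included casC, of the CRISPR interference complex, at 6.01-fold [3.32 to 11.6] and proX, of glycine betaine uptake, at 2.55-fold [2.41 to 2.69].

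Genes for type 1 fimbriae and the operons fhuACDB and argT-hisJQMP were lower in wild type with the dsrA plasmid. Of 9 measured fimbrial genes, 7 were at least 2-fold lower and 1, the recombinase gene fimE, was higher. The median of the fimbrial list was -3.25, outside the random range, and lay between -4.87 and -2.53 under the alternatives. The usher gene fimD was 15.4-fold lower [11.9 to 20.3]. In the fhuACDB operon, fhuB was 9.50-fold lower [7.12 to 12.9] and the operon median was -3.60. The other measured Fur-repressed iron acquisition genes did not share this difference, and the median of the whole list, -0.04, lay inside the random range. In the argT-hisJQMP operon for basic amino acid and histidine uptake, argT was 5.61-fold lower [4.94 to 6.39], 5 of 5 genes were at least 2-fold lower and the median was -2.04. In the comparisons that leave out wild type with vector, this operon had medians of -0.29 and -0.24, with 0 genes past 2-fold.

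Among the other genes reported as DsrA targets or tied to chromosome replication, none reached a 2-fold ratio with the plasmid in wild type. The log2 ratios were 0.60 for rbsD, of ribose use, -0.18 for mreB, of cell shape, -0.35 for lrp, a global regulator, and -0.43 for dnaA, the replication initiator. They were -0.14 for seqA and -0.33 for hda, which act on replication initiation. The median of the chromosome replication list was -0.20, at percentile 2.12, and it was outside the random range in 7 of 11 alternative settings. Sigma-32 heat-shock genes had a median of -0.03, inside the random range.

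**Figure D1:**
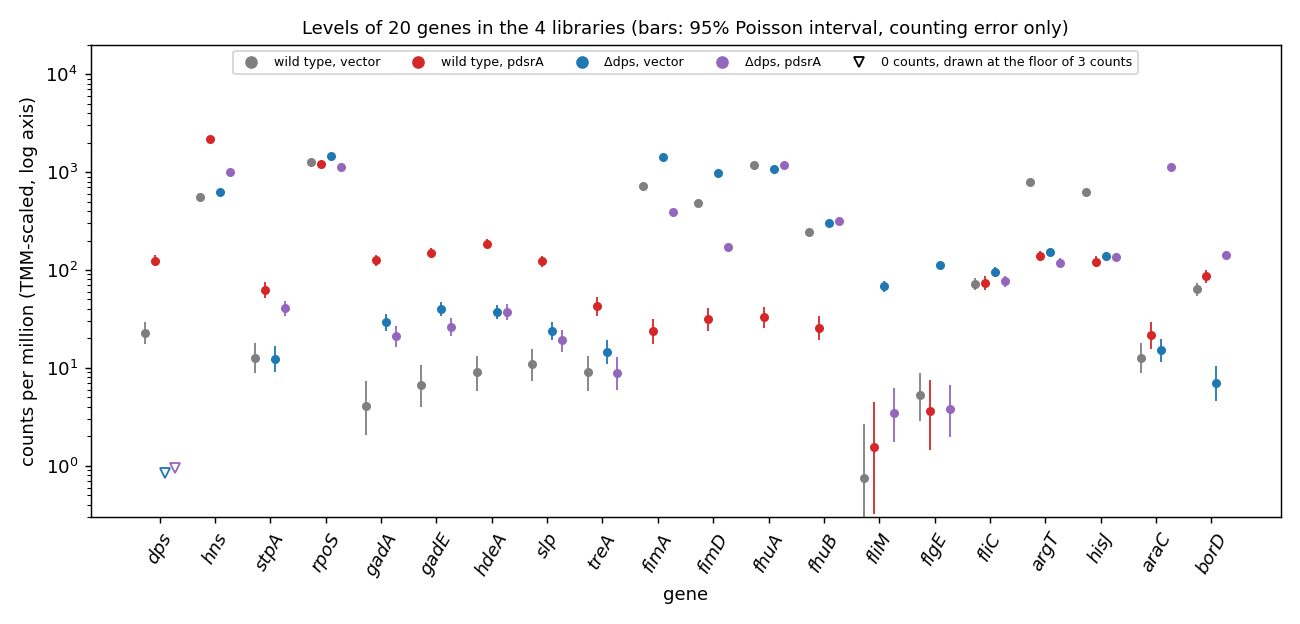
Scaled CPM (log axis) of 20 named genes in the 4 libraries, with 95% counting intervals as bars and open triangles for 0 counts drawn at the floor. dps was at 0 in both deletion libraries, fhuA stood at 33.0 CPM in wild type with the dsrA plasmid against 1168 with vector, and araC at 1135 CPM in the deletion with the dsrA plasmid.

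The same question was asked of the plasmid in the dps deletion strain. Here araC, the arabinose regulator, was 74.3-fold higher with the plasmid [56.8 to 99.1], from 54 to 3572 counts, and borD, a prophage lipoprotein gene, was 20.0-fold higher [13.4 to 31.3]. The rise of araC was not shared by 6 other arabinose genes, of which 2 had 50 or more counts. Their median log2 ratio was -0.31, with a range of -0.84 to -0.09. Genes for the flagellar hook and basal body were lower, among them flgE, the hook subunit, at 29.7-fold [16.8 to 57.9] and fliM, a motor switch protein, at 19.4-fold [10.7 to 39.4]. The acid resistance gene gadA and the receptor gene fhuA had log2 ratios of -0.48 and 0.14. Of 2728 measured genes, 10 were at least 2-fold higher and 35 at least 2-fold lower, or 4 and 9 with a filter of 200 counts and 6 higher with a prior count of 10.

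Of 51 flagellar and chemotaxis genes in the list, 28 were measured and 23 of these were at least 2-fold lower with the plasmid in the dps deletion. Their median log2 ratio was -3.23, with or without genes at 0 placed at their bound, and lay between -3.58 and -2.26 under the alternatives. The summed counts of all 51 genes were 3.92-fold lower [3.67 to 4.20]. With the plasmid, fliP and flgB had 0 counts and were at least 24.3-fold and at least 16.9-fold lower. The flagellar sigma factor gene fliA went from 93 counts to 1, a ratio of 82.8 [14.5 to 3306]. The flagellin gene fliC had a log2 ratio of -0.31. Of 9 measured fimbrial genes, 7 were at least 2-fold lower, with a median of -2.13, and fimD was 5.80-fold lower [5.29 to 6.36]. The gene stpA was 3.29-fold higher [2.32 to 4.75], lrhA, a repressor of the flagellar master operon, was 2.58-fold higher [2.09 to 3.19], and hns was 1.57-fold higher [1.49 to 1.66]. None of 23 RpoS-dependent genes reached 2-fold, with a median of -0.10 inside the random range, while the acid resistance median was -0.31 and that of H-NS-silenced genes -0.34, both outside it. The latter was outside in 10 of 11 alternative settings, with medians from -0.38 to -0.16. The log2 ratio of rpoS was -0.38, and those of rbsD, mreB, dnaA, seqA and hda were -0.06, 0.04, -0.06, 0.06 and 0.10.

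The comparison of the strains with the empty vector asked what the loss of dps changed without extra DsrA. Flagellar genes were higher in the deletion, with fliM at 240 counts against 2, a ratio of 90.7 [24.8 to 753], and flgE 21.6-fold higher [12.7 to 39.9]. The master regulator genes flhD and flhC were 6.12-fold [3.26 to 12.7] and 4.41-fold [2.85 to 7.11] higher, and lrhA was 2.17-fold lower [1.74 to 2.72]. Acid resistance genes were higher, with gadA at 7.15-fold [3.83 to 14.8] and hdeA at 4.16-fold [2.68 to 6.72]. The gene borD was 9.05-fold lower [5.93 to 14.4] and argT was 5.13-fold lower [4.67 to 5.65]. Of 2706 measured genes, 48 were at least 2-fold higher and 13, dps included, at least 2-fold lower, or 10 and 8 with a filter of 200 counts.

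Of the 51 flagellar genes, 28 were measured here and 24 of these were at least 2-fold higher in the deletion with vector. Their median was 3.08, with or without genes at 0 placed at their bound, and lay between 2.32 and 3.32 under the alternatives. Only 4 of the list were measured in the comparisons that leave out the deletion with vector, so most entered through their level in that library. The summed counts of all 51 genes were 3.79-fold higher [3.53 to 4.07]. Among them, flgC was at least 13.4-fold higher. The gene fliC was 1.31-fold higher [1.10 to 1.57], and 17 filament, motor and chemotaxis genes, of which 5 had 50 or more counts, had a median of 0.59. Of 12 measured acid resistance genes, 8 were at least 2-fold higher, with a median of 1.20 at percentile 100, and 23 RpoS-dependent genes had a median of 0.37 outside the random range with none at 2-fold. In the fimbrial list 3 of 9 were at least 2-fold higher, such as fimF at 2.80-fold [2.19 to 3.62], with a median of 0.99. The argT-hisJQMP operon had a median of -2.05, but of -0.29 with the plasmid in the deletion and -0.24 between strains with that plasmid. Log2 ratios were 0.17 for hns, 0.18 for rpoS, 0.24 for rbsD, -0.13 for mreB, -0.03 for dnaA, -0.06 for seqA and -0.02 for hda. This comparison and that of the plasmids in wild type use the same library of wild type with vector. The argT-hisJQMP differences in both rest on that shared library and are not separate results. The differences of the flagellar genes, borD and lrhA here and between the plasmids in the deletion rest on 1 shared library, the deletion with vector, and are not separate results.

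With the dsrA plasmid in both strains, the dps deletion was lower in acid resistance and RpoS-dependent genes. There gadA was 5.98-fold lower [4.54 to 7.98], gadE 5.72-fold lower [4.47 to 7.39] and treA, the periplasmic trehalase, 4.82-fold lower [3.10 to 7.68]. The gene hns was 2.21-fold lower [2.11 to 2.32]. Higher in the deletion were araC at 52.3-fold [38.6 to 72.8], fhuA at 35.8-fold [28.0 to 46.6] and fimA at 16.4-fold [12.3 to 22.6]. Of 2657 measured genes, 36 were at least 2-fold higher and 126, dps included, at least 2-fold lower, or 11 and 38 with a filter of 200 counts.

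Between the strains with the dsrA plasmid, 14 of 14 acid resistance genes and 16 of 25 RpoS-dependent genes were at least 2-fold lower in the deletion, with medians of -1.91 and -1.15, both at percentile 0. Of 11 H-NS-silenced genes, 6 were at least 2-fold lower and 1 higher, with a median of -1.16, and proX was 2.87-fold lower [2.72 to 3.03]. In the fimbrial list, 7 of 9 were at least 2-fold higher and 1 lower, with a median of 2.41 that lay between 1.88 and 3.43 under the alternatives. The 4 genes of the fhuACDB operon were at least 2-fold higher, with a median of 3.89, while the whole iron acquisition list had a median of -0.07, below its random range at percentile 1.13, and outside it in 9 of 11 alternative settings. The 4 measured flagellar genes had a median of 0.04, inside the random range, and the summed counts of all 51 were 1.12-fold higher [1.01 to 1.24]. Log2 ratios were -0.12 for rpoS, -0.42 for rbsD, 0.08 for mreB, 0.35 for dnaA, 0.13 for seqA and 0.41 for hda. This comparison and that of the plasmids in wild type use the same library of wild type with the dsrA plasmid, and the araC difference rests on the library of the deletion with that plasmid, as does that between the plasmids in the deletion.

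**Figure D2:**
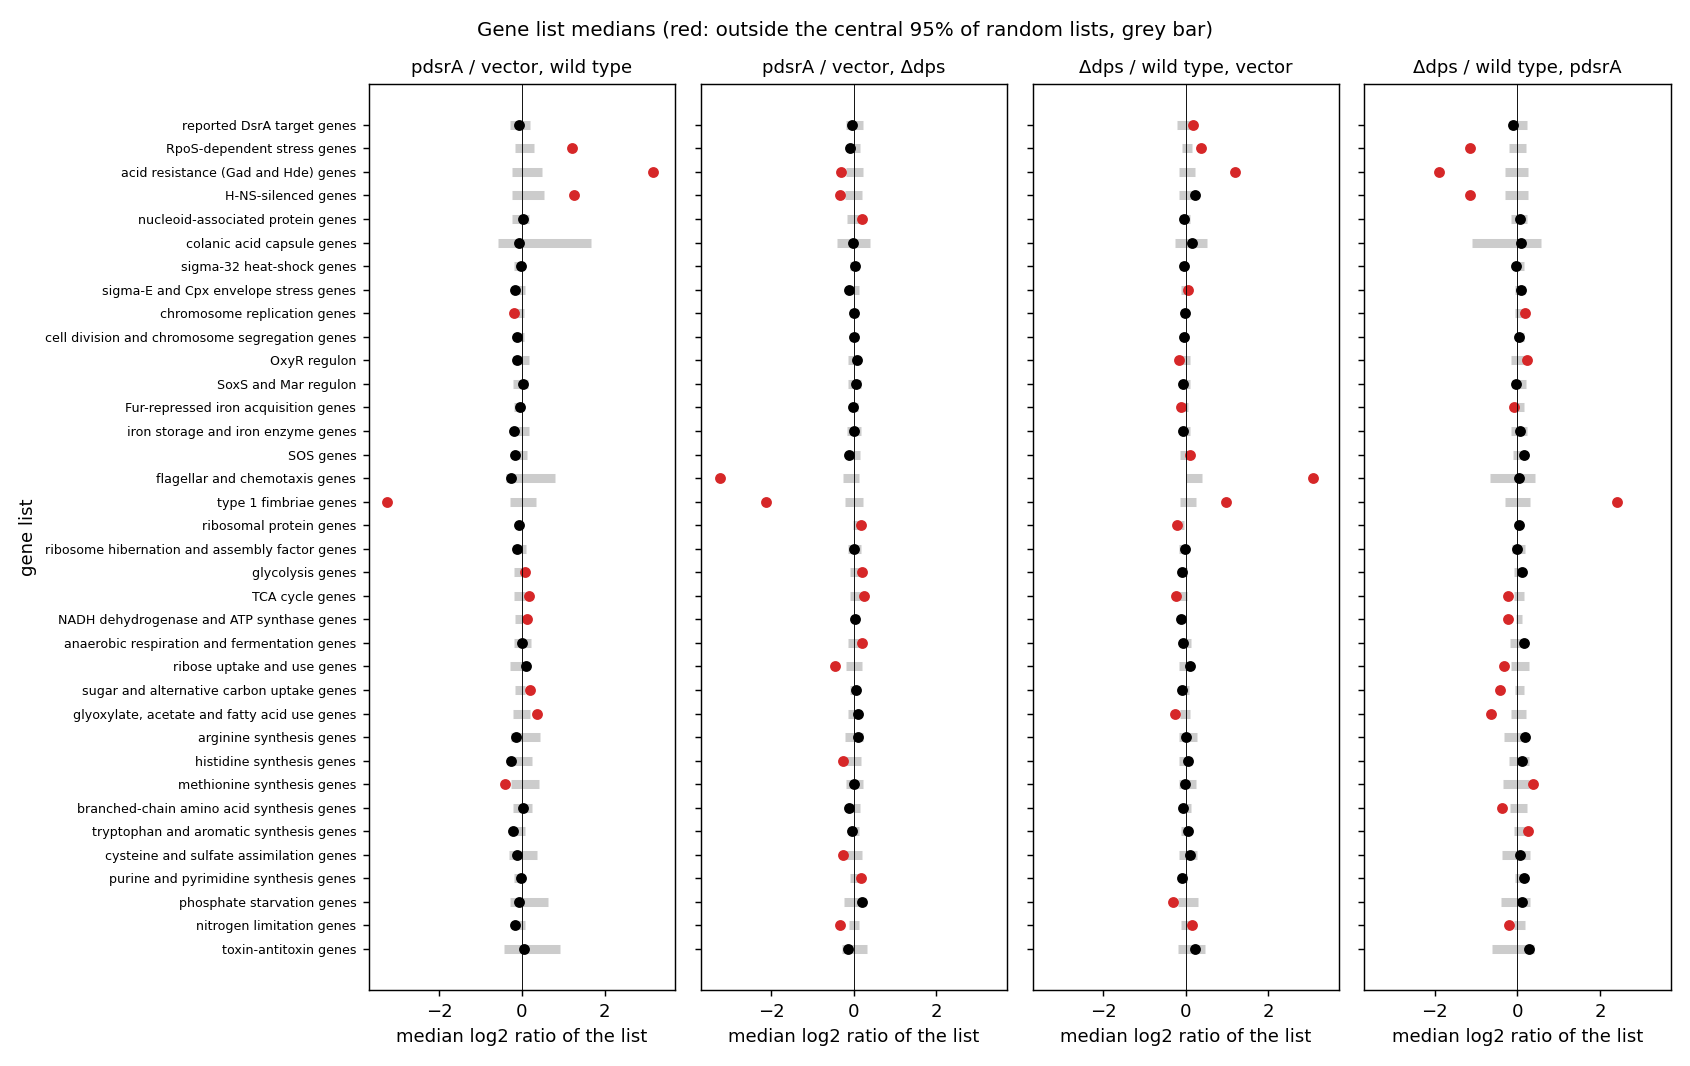
Median log2 ratios of 36 fixed gene lists in the 4 comparisons, with the central 95% of 10000 random lists in grey and medians outside it in red. The acid resistance median was 3.18 with the dsrA plasmid in wild type and -1.91 between the strains with that plasmid.

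The 2 by 2 layout also asks whether the plasmid difference itself differed between the strains. The log2 ratio in the deletion minus that in wild type was 5.41 for araC, 5.26 for fhuA and 3.77 for borD. It was -5.18 for gadA, -4.93 for gadE and -5.45 for fliF, of the flagellar basal body, and -1.32 for hns. Of 2762 measured genes, 80 differed at least 4-fold, and a filter of 200 counts left 28. The log2 ratio was larger in the deletion for 12, and larger in wild type for 68, among them dps with its 0 counts in the deletion. Of the 68, 19 were flagellar genes. The summed counts of the flagellar list with the plasmid in wild type were 0.865-fold those with vector [0.779 to 0.959]. The differences of the flagellar genes and borD rest on the library of the deletion with vector. The median difference was -3.07 over 14 acid resistance genes, -1.43 over 25 RpoS-dependent genes and -2.64 over 28 measured flagellar genes, all at percentile 0. Most of the 28 passed the count filter only through the deletion with vector, where they were high. Their percentile therefore follows largely from the filter and is no support of its own. From the summed counts of all 51 flagellar genes the difference was -1.76. No test of these differences against replicate variation was possible with 1 library per group.

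The plasmid ratios of the strains, which share no library, had a Pearson correlation of 0.16 and a Spearman correlation of 0.13 across 2761 genes, which are not independent replicates. Under filters of 10, 200 and 1 count the Pearson value was 0.074, 0.21 and 0.059, and the Spearman value 0.067, 0.21 and 0.045. Among 2521 genes measured in both, 135 were at least 2-fold higher in wild type and 7 in the deletion, and 1, stpA, in both, where 0.375 would be shared by independent draws. At least 2-fold lower were 27 and 8, and 7 fimbrial genes in both, against 0.0857. Of the 35 genes lower in the deletion, only these 8 were also measured in wild type. The 7 shared genes form 1 operon and move together, so the value for independent draws says little about them. The gene yjhF was at least 2-fold higher in wild type and at least 2-fold lower in the deletion, the only 1 to do so, against 0.428. The strain ratios under the plasmids had correlations of -0.03 and -0.07 across the same number of genes, and the former became 0.012 with a prior count of 0.5. Among 2600 genes measured in both strain comparisons, 8 acid resistance genes were at least 2-fold higher in the deletion with vector and at least 2-fold lower with the dsrA plasmid, against 0.858 by independent draws. These acid resistance genes are not independent of each other either. The genes fimD, fimF and fimG were higher in both, and acs and rpnB were lower in both.

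**Figure D3:**
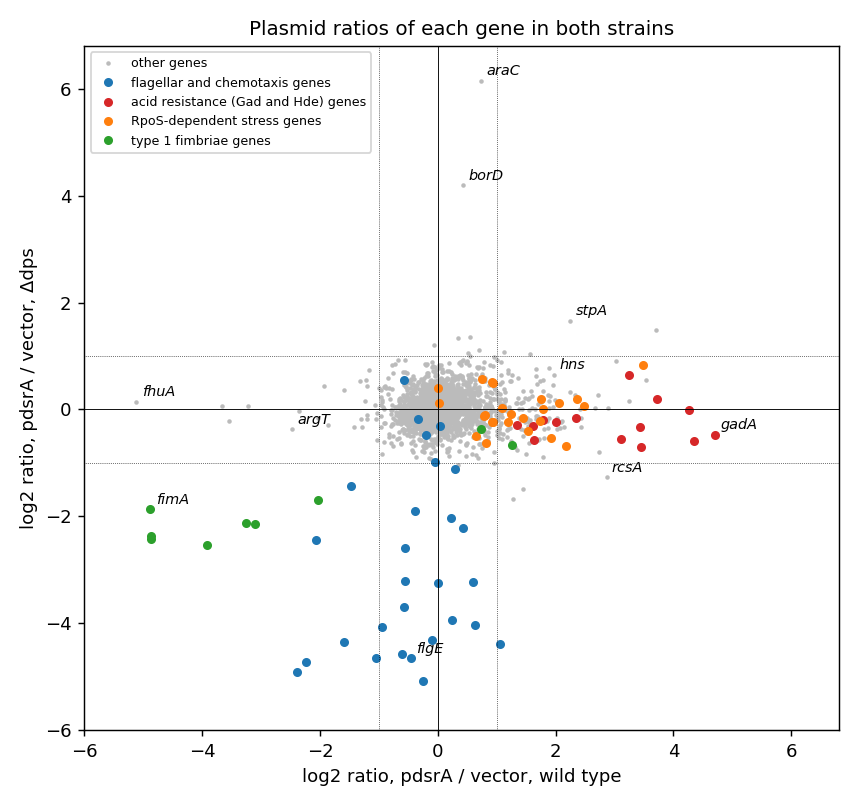
Log2 ratio of the dsrA plasmid over vector in wild type (horizontal) and in the dps deletion (vertical), 1 point per gene, with flagellar, acid resistance, RpoS-dependent and fimbrial lists coloured and dotted lines at a 2-fold ratio. Acid resistance genes lie to the right at a median of 3.18 in wild type, flagellar genes lie low at a median of -3.23 in the deletion, and 7 of 9 fimbrial genes lie to the lower left.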

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

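The tests in this part were chosen after the results were seen, except the thinning of the libraries, which was read as a test of depth only afterwards. The gene lists, the rules for counting and naming genes, and the 11 alternatives, thinning included, were chosen before the data were examined. Among the named genes and fixed lists, the ratio of the dsrA plasmid to vector lay in opposite directions in the strains for 13 genes and 2 lists. For the genes both counting intervals excluded a ratio of 1, for the lists both medians left their random range, and the difference was not tested because each group has 1 library. The log2 ratio in the deletion minus that in wild type was -5.18 for gadA, -4.93 for gadE, -4.15 for gadB, -3.66 for gadC, -4.13 for rcsA, the capsule regulator, -2.76 for bigA and -2.85 for treA. By the counting rule rcsA was not measured in wild type, where it had under 50 counts with either plasmid. The same difference was -2.45 for otsB, -1.93 for fimE, -1.66 for proX, -1.57 for proV and -1.57 for proW, and 5.26 for fhuA. The acid resistance median in the deletion minus that in wild type was -3.48, and the H-NS-silenced median -1.60, though in the deletion that list left its random range in 10 of 11 alternative settings. The ratio in the deletion was small for many of these genes, such as 0.14 for fhuA and -0.31 for proX, and no replicate shows whether its sign would repeat.

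In wild type the dsrA plasmid went with 164 higher and 27 lower genes. Reads spread evenly over the genome in that library could raise weak genes, and genes with 11 to 100 counts over the 4 libraries had a median log2 ratio of 0.37. Removing an even background of that size left 158 of the 164 genes at least 2-fold higher, which argues against it as the whole cause, and libraries thinned to 1 total gave 164 higher genes, 151 of them shared, which argues against depth. The same 164 genes had a median log2 ratio of -0.036 in the deletion, with a bootstrap interval over genes of -0.15 to 0.02. Their median in wild type was 1.56, which had to be at least 1 because the genes were chosen by that ratio. With 1 library per group, an effect of the plasmid in both strains, an effect that depends on dps and another state of a culture pool cannot be told apart.

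The fhuACDB operon was lower in wild type with the dsrA plasmid. Repression of iron acquisition as a class could lower it, but the lowest log2 ratio among the other 28 genes of that list was -0.47. Loss of a longer stretch of chromosome could also lower it, but the lower of the ratios of the flanking genes mrcB and hemL was -0.21. A change limited to this operon in that culture pool, by regulation or by mutation, stays open and untested.

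Flagellar genes were higher in the dps deletion with vector. An effect of the deletion whatever the plasmid could raise them. The summed counts of the 24 genes were 1.26-fold higher with the dsrA plasmid [1.03 to 1.55] against 10.3-fold with vector [9.05 to 11.8]. The 24 genes were chosen for being higher with vector, so the 10.3-fold is large by that choice. Over all 51 genes of the list the folds were 1.12 [1.01 to 1.24] and 3.79 [3.53 to 4.07]. The spread between culture pools is unknown. None of the 24 had 50 counts in either library with the dsrA plasmid, which is why sums were compared. Cells of a fully motile culture could also bring these transcripts, but fliC, abundant in such cells, gained 22.7 CPM, with a counting interval of 8.31 to 37.2, against 108 CPM, 96.5 to 119, for flgE. For this contrast flgE was taken as the most abundant of the hook and basal body genes counted as higher, so its gain is large by that choice. An effect of dps, with either plasmid or only without extra DsrA, and a state of this culture pool cannot be told apart with 1 library per group.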

How the results depend on the processing

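The 18 main results under the 11 alternatives set beforehand, with 1 chosen after seeing the data, gave 203 values, of which 166 stayed within the limit of change and 37 moved. The near-zero Pearson correlation of the strain ratios was the only 1 of them to change sign. For counts of genes or lists the limit was a fixed fold change. For correlations it was a 95% interval that treats genes as independent, which they are not, so whether a correlation moved is only a description. Most moves came from the count filter, which changes how many genes are measured. With filters of 10, 200 and 1 count in that order, the dsrA plasmid in wild type gave 363, 49 and 484 higher and 75, 14 and 149 lower genes. In the deletion it gave 58, 4 and 97 higher and 97, 9 and 138 lower genes. The deletion with vector gave 138, 10 and 199 higher and 41, 8 and 97 lower genes, and with the dsrA plasmid 105, 11 and 156 higher and 274, 38 and 370 lower genes. The difference between strains gave 182, 28 and 221 genes. A prior count of 10 gave 6 higher genes for the plasmid in the deletion. The Pearson correlation of the plasmid ratios was 0.074, 0.21 and 0.059 under the filters and 0.20 with a prior count of 0.5, and the Spearman correlation 0.067, 0.21 and 0.045 under the filters. The strain ratios had a Pearson correlation of 0.012 with a prior count of 0.5 and a Spearman correlation of -0.0061 with a filter of 200, and the cause was not tested.

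With the even background removed, chosen after seeing the data, the plasmid in wild type gave 162 higher and 30 lower genes. The filters leave a gene's own ratio as it is. Of 2976 values of the 210 named genes under the other 8 alternatives, 2926 stayed inside their counting interval. Of the 1264 values of genes counted as higher or lower, 0 changed sign and 14 fell below the limit. Sign changes of genes not counted were not recorded. Depth limits genes under 50 counts, and of the 164 higher genes in wild type, 127 had under 100 counts with vector. No paired analysis was possible because each group has 1 library.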

Other observations

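The lists outside the random range, of 36, were 11 for the plasmid in wild type, 14 for the plasmid in the deletion, 14 between strains with vector and 16 between strains with the dsrA plasmid. If the genes of a list moved independently, 1.8 of 36 would lie outside in each comparison. Genes of an operon do not, and some lists share members. Ribosomal protein genes had a median log2 ratio of 0.17 with the plasmid in the deletion and -0.20 between strains with vector, which share the library of the deletion with vector. In the comparisons without that library the medians were -0.07 and 0.05, inside the random range. For the other lists too, values from comparisons that share a library are not separate observations. Genes of the TCA cycle had medians of 0.18 and 0.25 with the plasmid in wild type and the deletion, and of -0.24 and -0.23 between strains with vector and with the dsrA plasmid. Sugar and alternative carbon uptake genes had medians of 0.19 with the plasmid in wild type and -0.42 between strains with the dsrA plasmid, and the genes of glyoxylate, acetate and fatty acid use had 0.36 and -0.63. Within the last group fadH, of unsaturated fatty acid breakdown, was 3.40-fold higher with the plasmid in wild type [2.16 to 5.48].

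Methionine synthesis genes had a median of -0.41 with the plasmid in wild type, outside the random range in 10 of 11 alternative settings, and 0.38 between strains with the dsrA plasmid, and ribose genes had -0.44 with the plasmid in the deletion. Nitrogen limitation genes had -0.33 there. Heat-shock genes of sigma-32 had medians of -0.03, 0.02, -0.03 and -0.04 in the 4 comparisons, all inside the random range. Curli genes had no member with 50 counts, 1 of 28 Hfq and small RNA entries and 0 of 22 ribosomal RNA entries matched the table, so no median was placed for these lists. KEGG pathways, examined after the data were seen, lay outside the random range in 20 of 74 cases for the plasmid in wild type, 23 of 77 in the deletion, 15 of 77 between strains with vector and 22 of 74 with the dsrA plasmid, and in 17 of 77 for the difference.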
